A study of Sus scrofa domesticus with 34 samples.

How the data were processed

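The series holds 34 libraries labelled muscle from pigs on 4 diets. Per the labels' protocols, tissue was kept frozen, RNA was isolated with Trizol, and libraries were made with a QuantSeq 3′ forward kit, in which each read stands for the 3′ end of a polyadenylated transcript, so that counts do not scale with transcript length. Per the submitters' processing notes, FastQC, TopHat, HTSeq and DESeq2 were used. Their versions, the genome build and the annotation are not given in the sources used here. The deposited values are raw read counts per gene with no normalization, 1 file per library, for 31907 genes named by Ensembl identifiers. Each file also ends with 5 lines of HTSeq categories, which were left out of library sizes and tests. Of all reads counted in a file, 16.4 to 29.9% lay outside annotated features, 3.63 to 4.68% were ambiguous between features and 11.2 to 20.7% aligned to more than 1 place, and the categories for unaligned and low-quality reads were at 0. Reads from near-identical genes would fall in the multiple-alignment category, so that genes with close copies are undercounted. Whether reads were counted by strand is not given in the sources used here.

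Diet was taken from the labels, and the feed doses from the description of the series. Replicate numbers are in accession order and pair no samples. The description of the series counts individuals per diet, so that p-values are meant to measure the spread between animals. A limit for the libraries of file numbers 30 to 34 is given below. No files were identical. The highest correlation of log2 CPM between libraries was 0.979 over 561 pairs. The closest pair by a chi-square test of counts was 25(OH)D replicate 8 and combination replicate 5, both of file numbers 30 to 34. Its value was 2.38 per gene, above the 1 expected from sampling alone and below the median of 31.5 over pairs. This value falls with lower depth, and depth was lowest in those file numbers. Gene symbols came from a table of identifiers and symbols, which matched 15029 of the 31907 identifiers. Gene coordinates were not used here.

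All comparisons used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test) on the deposited counts, with TMM scaling, edgeR's expression filter by diet and a model of diet and sex over all 34 libraries. The filter kept 13974 genes, 11134 of them with a symbol. P-values were two-sided and adjusted by the Benjamini-Hochberg method within a comparison, with 0.05 as the threshold. Standard errors were derived from the F statistic, and 95% intervals from a t distribution with 36.0 degrees of freedom. The interaction was an F-test of 3 terms. For gene lists, limma 3.58.1 camera was run on log2 CPM (prior count 3) with a preset correlation of 0.01, and again with an estimated correlation. Limma's fry, a test of whether the genes of a list move on balance in 1 direction, was a further alternative. No called list held with an estimated correlation or by fry. Of 29 lists, 27 had at least 5 tested members and were tested. The lists, tests and alternatives were fixed before the data were examined, and so was the rule for named genes. It takes up to 10 genes per direction among those past the threshold in each comparison, and where fewer than 10 pass, also the 5 with the smallest unadjusted p, given as values. VDR, CYP24A1, CYP27B1, CYP2R1, MYH7, MYH4, ADIPOQ and FBXO32 were to be given if measured, and for sex up to 5 genes per direction and the measured Y chromosome genes. A further 7 lists (skeletal muscle, neurons, oligodendrocytes, astrocytes, cerebellum, forebrain and liver) were written after the data were examined. Of the 28 genes of the skeletal muscle list, 18 are also in a list fixed earlier, 16 of them in the fast-twitch list. The same holds for 3 of 14 oligodendrocyte, 3 of 12 astrocyte and 1 of 16 cerebellum genes, and for 0 of the neuron, forebrain and liver genes. CPM of marker genes and list scores use total gene counts, and CPM of genes named in the diet comparisons use TMM-scaled library sizes, so that a gene given in both ways has slightly different values. Some items that these rules name are not reported here. Library measures were compared by exact permutation of the group labels.

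The scripts were tested on simulated counts with the means, library sizes and dispersions of the real libraries and 200 changed genes. For 25(OH)D against standard cholecalciferol (13613 genes), edgeR recovered 26.9% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 6 false calls among 118. For the combination against increased cholecalciferol (13530 genes) the shares were 20.9%, 53.7% and 87.9%, with 1 false call among 109. For increased against standard cholecalciferol (13579 genes) they were 22.4%, 64.2% and 95.5%, with 5 false calls among 126. For the interaction (13584 genes, 1 diet changed in females) they were 0%, 8.96% and 48.5%. The simulated genes vary independently of each other, unlike real ones.

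The alternatives planned before the data were examined were RLE size factors, no low-count filter, a filter of at least 1 CPM in at least 8 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, no sex term, only the libraries of the groups compared, a term for the 3 runs of file numbers, and only file numbers 1 to 24. Those added afterwards were the regional difference as a covariate, the regional difference and the muscle list as covariates, and fits without the 6 libraries with the fewest detected genes, without the 15 libraries with a regional difference above 1, and without combination replicate 3. The muscle list was also compared without file numbers 30 to 34, within file numbers 1 to 24 and without each library in turn.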

Results

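Gene expression was measured by 3′ mRNA sequencing in 34 libraries from pigs, 1 library per animal, each labelled as muscle. QuantSeq counts 1 fragment near the 3′ end of each polyadenylated transcript. The animals received 1 of 4 diets that differed in the dose and the chemical form of vitamin D. Cholecalciferol is vitamin D3, and 25(OH)D, or calcidiol, is the same molecule with a hydroxyl group on carbon 25, which the liver normally adds. The control diet (standard cholecalciferol, n = 8, 4 females and 4 castrated males) held 2000 IU of cholecalciferol per kg feed in the grower phase and 1500 IU in the finisher phase. The increased cholecalciferol diet (n = 10, 6 females and 4 castrated males) held 3000 and 2500 IU. The combination diet (n = 8, 4 females and 4 castrated males) held the control dose of cholecalciferol plus 1000 IU of 25(OH)D in both phases. The 25(OH)D diet (n = 8, 4 females and 4 castrated males) held 2000 and 1500 IU of 25(OH)D and no cholecalciferol.

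Total gene counts per library ran from 1.34 to 30.4 M (M, mega), with a median of 6.67 M. The medians were 7.50 M for the control diet, 7.19 M for increased cholecalciferol, 3.39 M for the combination and 6.56 M for 25(OH)D. Depth stepped with the numbering of the deposited files. File numbers 1 to 24 held 4.08 to 13.2 M counts, numbers 25 to 29 held 16.8 to 30.4 M and numbers 30 to 34 held 1.34 to 2.69 M. The run with the lowest depth held 4 of the 8 combination libraries, 1 of the 25(OH)D libraries and none of the other diets, so that depth and diet overlapped in part. Total counts, detected genes, the share of mitochondrially encoded transcripts and the share of the 10 most abundant genes were compared between all pairs of diets. None of the 24 two-sided exact permutation tests passed after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.206. Before adjustment, detected genes differed from the control by −1404 with the combination (p = 0.0250) and by −1128 with 25(OH)D (p = 0.0177). Total counts differed by −5.22 M between 25(OH)D and the control (p = 0.0452). The mitochondrial share was higher with 25(OH)D than with increased cholecalciferol (p = 0.0487) and the combination (p = 0.0258).

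Transcripts of neurons and glia were abundant in the 34 libraries labelled muscle. MBP, which encodes a myelin protein, averaged 3361 ± 1643 CPM (counts scaled to a library total of 1 M; mean ± SD, n = 34). STMN2 (1560 ± 508 CPM) and SNAP25 (1413 ± 583 CPM) encode neuronal proteins, and GFAP (1216 ± 672 CPM) and AQP4 (720 ± 200 CPM) mark astrocytes. MOG, a myelin gene of oligodendrocytes, averaged 83.5 ± 35.3 CPM. Skeletal muscle transcripts were present as well. ACTA1, the skeletal muscle actin, averaged 1645 ± 957 CPM, TNNC2, the fast troponin C, 943 ± 393 CPM and CKM, the muscle creatine kinase, 339 ± 180 CPM. The mean log2 CPM of a list of abundant skeletal muscle transcripts was 5.92 ± 0.53, against 7.93 ± 0.23 for neurons, 7.45 ± 0.58 for oligodendrocytes and 8.48 ± 0.21 for astrocytes. The muscle list lay below each of those lists in all 34 libraries. These lists were written after the counts had been examined. The most abundant feature, at 106599 ± 31659 CPM, was ENSSSCG00000048719, which the name table does not pair with a symbol, and most of the other leading transcripts were encoded by mitochondrial DNA, such as ATP6 at 55985 ± 19700 CPM.

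**Figure D1:**
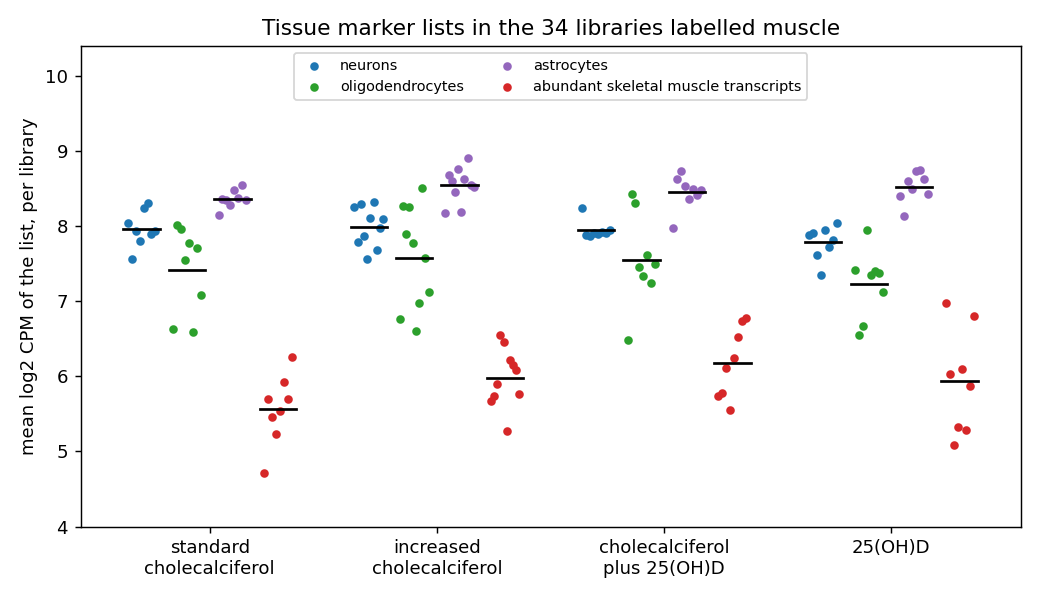
Mean log2 CPM of 4 marker lists (vertical axis) in each library, by diet (horizontal axis). Points are libraries, and bars are the means of 8 to 10 libraries. The muscle list lies below the other lists in all 34 libraries and spans 4.71 to 6.98.

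Libraries of 1 diet also differed among themselves in transcripts of particular brain regions. CBLN1 and CBLN3, expressed in cerebellar granule cells, ranged from 118 to 1172 CPM and from 88.7 to 1146 CPM. TBR1 and FEZF2, transcription factors of the cerebral cortex, ranged from 1.74 to 62.9 CPM and from 0.152 to 17.8 CPM. The mean log2 CPM was 4.99 ± 1.03 for a cerebellum list and 3.69 ± 1.07 for a forebrain list (SD, n = 34), and their difference ran from −0.95 to 5.35. The range inside each diet was at least 5.06, and the mean difference was 1.47 ± 2.62 for the control diet, 0.90 ± 1.99 for increased cholecalciferol, 2.00 ± 1.75 for the combination and 0.94 ± 1.91 for 25(OH)D (SD, n = 8 to 10). A list of abundant liver transcripts averaged 1.87 ± 1.06, with ALB (albumin) at 12.8 to 818 CPM. None of the 48 exact permutation tests of these lists and of the regional difference between diets passed after adjustment (smallest adjusted p = 0.738).

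**Figure D2:**
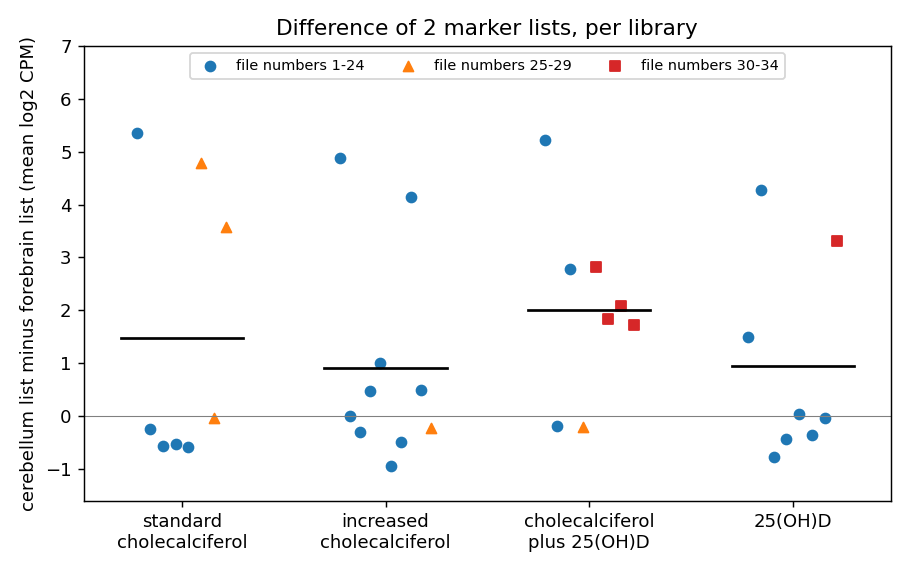
Difference between the mean log2 CPM of the cerebellum list and the forebrain list (vertical axis) in each library, by diet (horizontal axis). Symbols give the run of deposited file numbers and bars the mean of each diet. Values run from −0.95 to 5.35, and the range inside each diet is at least 5.06.

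Sex was tested across all 34 libraries with diet in the model, which also checks the labels. Genes were lower in the 18 females than in the 16 castrated males in 11 cases and higher in none (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, 13974 genes tested, 919 at an unadjusted p below 0.05, where 699 would be expected by chance); DESeq2 called 15 and limma-voom 11. The genes with a symbol were KDM5D (ENSSSCG00000032354), a histone demethylase gene of the Y chromosome (log2 fold change −2.29, SE 0.42, adjusted p = 0.00595), and EIF1AY (ENSSSCG00000037509), a translation factor gene of the Y chromosome (−1.71, SE 0.27, adjusted p = 0.000405). The other 9 have no symbol in the name table. EIF1AY reached 3.05 ± 1.79 CPM in females (SD, n = 18) and 9.41 ± 3.19 CPM in castrated males (SD, n = 16), so that females were not at 0. Summed over the 11 genes, the level was 40.6 ± 15.7 CPM in the 14 females outside file numbers 30 to 34 (SD), 136 ± 35.9 CPM in the 4 females within them and 238 ± 66.9 CPM in the castrated males. The females of that run overlapped the castrated males, of which the lowest had 121 CPM.

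**Figure D3:**
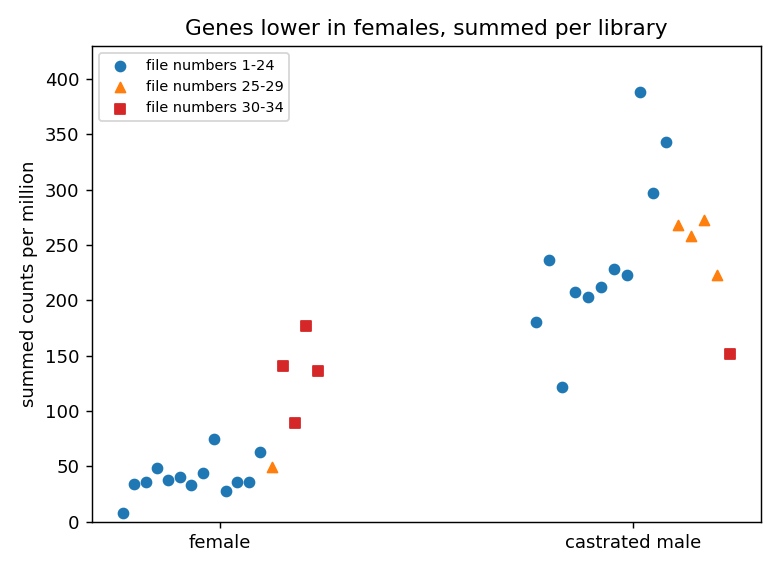
Summed CPM of the 11 genes that were lower in females (vertical axis, from 0) in each library, by sex (horizontal axis), with symbols for the run of deposited file numbers. The 14 females outside numbers 30 to 34 lie at 8.02 to 74.9 CPM and the 4 females within them at 89.3 to 177 CPM.

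The first diet question was the dose of cholecalciferol, 3000 and 2500 IU against 2000 and 1500 IU per kg. No gene differed between increased and standard cholecalciferol after adjustment. The named genes with the smallest p-values were ZNHIT1, a subunit of a chromatin remodelling complex (log2 fold change 0.46, SE 0.11), PIGC, of glycosylphosphatidylinositol anchor synthesis (−0.41, SE 0.11), MED17, a Mediator subunit (−0.61, SE 0.16), the zinc transporter gene SLC30A9 (−0.56, SE 0.15) and the splicing regulator gene RBFOX2 (−0.44, SE 0.12), each with an adjusted p of 0.623. SCD, which encodes the desaturase that makes monounsaturated fatty acids, stood at −0.39 (SE 0.12), and was the only member of the lipid synthesis list and of the adipocyte list that passed when adjusted over the list alone (adjusted p = 0.0435 and 0.0244), with 0 members of either passing over all genes tested. Adjustment over a list alone does not allow for the number of lists and comparisons, so that some members pass by chance. In each comparison of diets, 1 to 3 of the 27 lists tested held such a member. Of 27 gene lists, camera with a preset correlation called the fast-twitch fibre genes higher (12 of 14 tested members above 0, mean log2 fold change 0.29, adjusted p = 0.00251) and the mitochondrially encoded proteins lower (11 of 13 below 0, mean −0.29, adjusted p = 0.0326). Examples are MYOZ1 (0.78, SE 0.27) and MYL1 (0.65, SE 0.27), of the sarcomere, and ND2 (−0.60, SE 0.25), of respiratory complex I. With an estimated correlation both had an adjusted p = 0.927. The mean of the muscle list, which shares 16 of its 28 listed genes with the fast-twitch list, differed by 0.41 between the diets (exact permutation p = 0.0543 before and 0.738 after adjustment), and by 0.68 within file numbers 1 to 24. At an unadjusted p below 0.05 there were 1086 genes, where 699 would be expected by chance in this and each further comparison of diets; DESeq2 and limma-voom also called 0.

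Addition of 1000 IU of 25(OH)D to the control diet was tested by the combination against standard cholecalciferol. No gene passed after adjustment. Small p-values among named genes belonged to CPA1 (ENSSSCG00000016557), which encodes a pancreatic carboxypeptidase (2.61, SE 0.66), LASP1, an actin-binding protein gene (−0.44, SE 0.11), DPP3, a peptidase gene (−0.53, SE 0.14), and RAB5IF (−1.64, SE 0.44), all with an adjusted p of 0.999. POSTN, a matrix protein gene, passed in the extracellular matrix list when adjusted over the list alone (2.40, SE 0.71, adjusted p = 0.0487). Camera called 4 lists: fast-twitch fibre genes higher (13 of 14 above 0, mean 0.47, adjusted p = 3.12e-09), slow-twitch fibre genes higher (6 of 10, mean 0.34, adjusted p = 0.0451), extracellular matrix and fibroblast genes higher (21 of 28, mean 0.46, adjusted p = 0.0218) and mitochondrially encoded proteins lower (13 of 13, mean −0.37, adjusted p = 0.000939). Members with the values behind these calls include TNNT3 (0.76, SE 0.29), TNNC2 (0.67, SE 0.25), TNNC1 (1.25, SE 0.48), COL3A1 (1.16, SE 0.46) and ND3 (−0.59, SE 0.24). With an estimated correlation the adjusted p was 0.338 for both fibre lists and 0.717 for the other lists. The mean of the muscle list differed by 0.62 (exact permutation p = 0.0196 before and 0.738 after adjustment). That list stood at 6.25 to 6.80 in the 5 libraries of file numbers 30 to 34, 4 of them from the combination, and without that run the difference was 0.23 (exact permutation p = 0.392, n = 4 and 8). Within file numbers 1 to 24, which also leave that run out, it was 0.55 (exact permutation p = 0.0536, n = 3 and 5). There were 607 genes at an unadjusted p below 0.05, fewer than the 699 expected by chance, and DESeq2 and limma-voom called 0. Without combination replicate 3, the library with 145 CPM of CPA1, CPA1 was at 0.82, the mean of the extracellular matrix list was −0.01, and of the 4 lists the fast-twitch genes alone were called. A term for the runs of file numbers ended the calls of both fibre lists and of the mitochondrial list.

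The 2 molecules were compared at matched doses of 2000 and 1500 IU by 25(OH)D against standard cholecalciferol. No gene passed after adjustment. FADS1 (ENSSSCG00000024015), which encodes the delta-5 desaturase of polyunsaturated fatty acid synthesis, had the smallest p, with 47.4 ± 15.1 CPM against 28.8 ± 4.58 CPM (SD, n = 8 each). Its log2 fold change was 0.72 (SE 0.16, 95% interval 0.39 to 1.04) with an adjusted p of 0.938 over all genes and 0.00107 when adjusted over the list alone (lipid synthesis). FADS1 also averaged above the control with increased cholecalciferol (36.3 ± 8.17 CPM) and with the combination (39.2 ± 5.78 CPM). All diets are set against the same 8 control libraries, so that control values apart by chance would put every diet on the same side. The combination also holds 25(OH)D. Whether a difference from the control is particular to the molecule can therefore not be told from these means. ATP6V1B2, a proton pump subunit gene (−0.58, SE 0.16), SNX14 (−0.54, SE 0.16), SPATA2 (−0.56, SE 0.17) and LRRIQ3 (2.01, SE 0.61) followed. ATP6V1B2, SPATA2 and LRRIQ3 likewise lay on the same side of the control in both of those diets, and LRRIQ3 averaged at most 1.31 CPM in any diet. SNX14 stayed near the control there (28.4 and 28.6 CPM against 29.4 CPM). VDR (ENSSSCG00000020864), the vitamin D receptor gene, averaged 2.03 ± 0.849 CPM against 3.85 ± 2.18 CPM, and its difference was −0.98 (95% interval −1.73 to −0.23, unadjusted p = 0.0122, adjusted p = 1.00). CYP2R1 (ENSSSCG00000013389), which encodes the main 25-hydroxylase of vitamin D, was at 0.64 (95% interval 0.07 to 1.21, unadjusted p = 0.0284, adjusted p = 1.00). FBXO32, an atrophy-related ubiquitin ligase gene, was at 0.07 (95% interval −0.37 to 0.52). Camera called the fast-twitch fibre genes higher (12 of 14 above 0, mean 0.39, adjusted p = 7.07e-06), with MYL1 at 0.77 (SE 0.28) and ACTN3 at 0.61 (SE 0.25). The adjusted p was 0.676 with an estimated correlation. Each comparison with the control called this list higher, and these comparisons share the 8 control libraries, while no pair of the other diets called it. The muscle list averaged 5.57 in the control and 5.94 to 6.18 in the other diets. The mean of the muscle list differed by 0.37 (exact permutation p = 0.233). With each library left out in turn it ran from 0.22, without 25(OH)D replicate 1, to 0.49, without 25(OH)D replicate 3, and it was 0.25 without 25(OH)D replicate 8 and 0.48 within file numbers 1 to 24. There were 452 genes at an unadjusted p below 0.05 (699 expected by chance), and DESeq2 and limma-voom called 0. The 95% interval excluded a 2-fold difference in either direction for 73.9% of the tested genes, so that a larger effect remained possible for the rest.

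**Figure D4:**
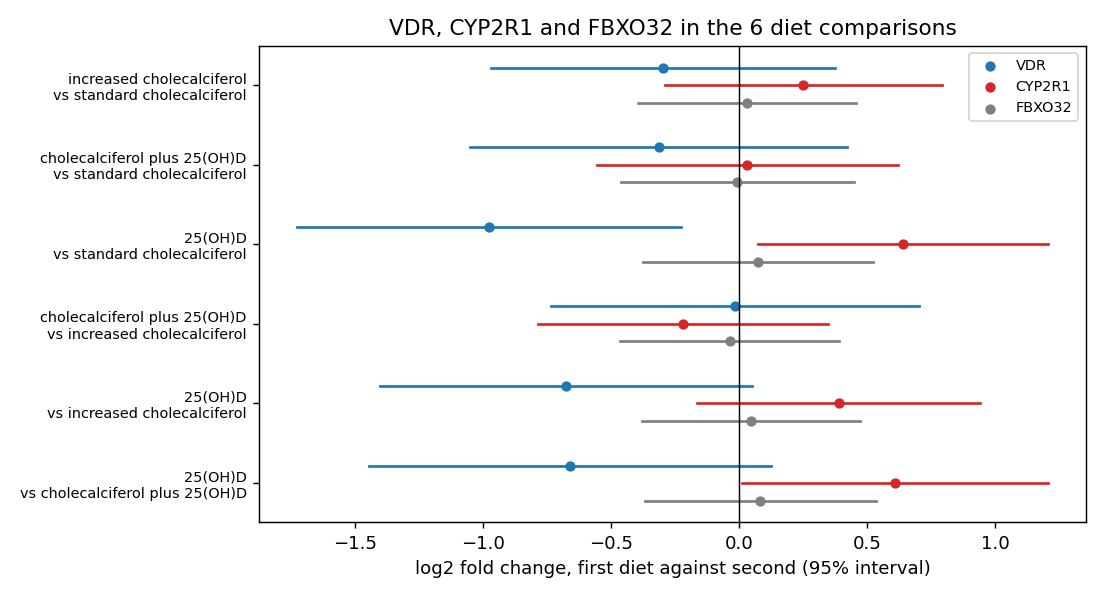
Log2 fold changes of VDR, CYP2R1 and FBXO32 (horizontal axis) in the 6 diet comparisons (vertical axis). Points are estimates and lines 95% intervals from the edgeR fit of 34 libraries. The VDR estimate for 25(OH)D against standard cholecalciferol is −0.98, and no gene shown passed after adjustment.

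At matched total doses of 3000 and 2500 IU, the combination was compared with increased cholecalciferol, so that the added 1000 IU was either molecule. No gene passed after adjustment, and no gene list was called. Small p-values were those of CPA1 (2.58, SE 0.60, adjusted p = 0.865), EPN2, an endocytic adaptor gene (−0.68, SE 0.17, adjusted p = 0.865), SCARB1, which encodes a lipoprotein receptor (−0.65, SE 0.17, adjusted p = 0.931), and ZNF514 (0.68, SE 0.18, adjusted p = 0.931). MYH3, an embryonic myosin gene (1.11, SE 0.34), passed in the list of myogenic regulators when adjusted over the list alone (adjusted p = 0.0185). VDR differed by −0.02 (95% interval −0.74 to 0.70), CYP2R1 by −0.22 (−0.79 to 0.35) and FBXO32 by −0.04 (−0.47 to 0.39). There were 578 genes at an unadjusted p below 0.05 (699 expected by chance), DESeq2 and limma-voom called 0, and the 95% interval excluded a 2-fold difference for 73.9% of the tested genes. A term for the runs of file numbers gave 1 gene higher with the combination, and the 24 libraries of file numbers 1 to 24 gave 2, of which CPA1 was the one with a symbol (3.55, SE 0.63, adjusted p = 0.0426, against 0.0426 to 1.00 over all alternatives that gave one). Without combination replicate 3, CPA1 was at 0.70.

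In the remaining pairs both dose and molecule differed. Between 25(OH)D and increased cholecalciferol no gene passed after adjustment, with 1672 genes at an unadjusted p below 0.05 (699 expected by chance) and 0 calls by DESeq2 or limma-voom. The named genes with the smallest p-values were YPEL2 (−0.66, SE 0.15), VGF, a neurosecretory protein gene (−0.61, SE 0.15), OAT, which encodes ornithine aminotransferase (−0.89, SE 0.22), COX18, of cytochrome oxidase assembly (0.86, SE 0.22), and RIOK3 (−0.55, SE 0.14), each with an adjusted p of 0.306. Camera called the mitochondrially encoded proteins higher (13 of 13 above 0, mean 0.39, adjusted p = 9.69e-05) and the immediate early genes lower (14 of 20 below 0, mean −0.47, adjusted p = 0.0176). ND2 (0.68), ND3 (0.64), ND4 (0.64) and ND5 (0.39) passed when adjusted over the list alone (adjusted p = 0.0480 each), whereas FOS (−1.13, SE 0.38), EGR1 (−0.97, SE 0.36) and NR4A1 (−0.84, SE 0.30), transcription factors induced within minutes of a stimulus, did not pass, and JUN of the same list was at 0.87 (SE 0.40). L1CAM of the nerve and Schwann cell list (−0.61, SE 0.20) also passed when adjusted over the list alone, and so did EPB42 of the red blood cell list (0.88, SE 0.25), which had fewer than the 5 tested members that the test of lists required. With an estimated correlation the adjusted p was 0.936 for both called lists. Mitochondrially encoded transcripts took 26.8 ± 7.29% of counts with 25(OH)D and 21.3 ± 3.72% with increased cholecalciferol (SD, n = 8 and 10; exact permutation p = 0.0487 before and 0.234 after adjustment).

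Between 25(OH)D and the combination no gene passed after adjustment, with 1058 genes at an unadjusted p below 0.05 (699 expected by chance) and 0 calls by DESeq2 or limma-voom. Small p-values were those of ANKRD13B (0.70, SE 0.16), TMEM255A (−1.64, SE 0.40), the sialyltransferase gene ST6GALNAC4 (0.69, SE 0.18) and PLA2G1B, the pancreatic phospholipase gene (−3.85, SE 0.99), each with an adjusted p of 0.653. Camera called the mitochondrially encoded proteins higher (13 of 13 above 0, mean 0.47, adjusted p = 8.38e-07) and the proteasome subunits lower (22 of 27 below 0, mean −0.13, adjusted p = 0.0241). ND1 to ND4 (0.59 to 0.73), PSMB2 (−0.73, SE 0.22) and the complex I gene NDUFC2 (−2.51, SE 0.67) passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.828 for the mitochondrial list and 0.640 for the proteasome list. In file numbers 1 to 24, with 3 combination libraries, 8 genes were lower with 25(OH)D, among them the pancreatic enzyme genes PNLIP (−5.29, SE 1.03), CPA1 (−3.35, SE 0.65) and PLA2G1B (−5.21, SE 0.98), of which PNLIP is named after its values were seen. Without combination replicate 3, in the fit of all other libraries, PLA2G1B was at −1.45 and TMEM255A at −0.91.

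Of the 16 listed genes of vitamin D metabolism and signalling, 12 were tested. Camera called neither that list nor the list of canonical VDR target genes (13 of 20 tested) in any diet comparison. Against the control diet, the adjusted p of the VDR target list was 0.929 for increased cholecalciferol, 0.330 for the combination and 0.845 for 25(OH)D. Some other genes of vitamin D metabolism were near the detection limit. CYP24A1, the 24-hydroxylase gene induced by active vitamin D, had 43 counts over all 34 libraries and CYP27B1, the 1-alpha-hydroxylase gene, 15, so that a diet difference in either was not detectable at this depth. ADIPOQ, the adipocyte hormone gene, had 147 counts. MYH7 and MYH4 have no identifier in the name table and were not analysed here. No gene showed a sex by diet interaction (0 of 13974 after adjustment by the edgeR quasi-likelihood test, 384 at an unadjusted p below 0.05, where 699 would be expected by chance, 0 by DESeq2 and by limma-voom).

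The 3 comparisons with the control diet shared the 8 control libraries, and the correlation of their log2 fold changes across genes, which are not independent replicates, was set against 10 simulations with no diet effect. Increased cholecalciferol and the combination had r = 0.515 (simulated mean 0.504) and a covariance of 0.0525 (simulated mean 0.0495). Increased cholecalciferol and 25(OH)D had r = 0.295 (simulated mean 0.512) and a covariance of 0.0285 (simulated mean 0.0493). The combination and 25(OH)D had r = 0.245 (simulated mean 0.467) and a covariance of 0.0239 (simulated mean 0.0490). With the controls split into 4 and 4, the mean r over 10 splits was −0.0206, −0.183 and −0.209. There were 0 shared calls, since none of the 3 comparisons had a call. The genes of these simulations also vary independently of each other, unlike real ones. A gap between an observed and a simulated value is therefore no evidence for or against a diet effect.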

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

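The explanations in this part were tested after the values had been seen, except the test of further regional genes, whose lists were written before it was run. A library was singled out where its gap to the nearest library of its diet was large against the range of that diet. Of 172 tests of this kind, 14 stood out, and chance gives about 1 in 20.

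Total gene counts (M, mega) stood apart in increased cholecalciferol replicate 10 (21.0 M), combination replicate 4 (30.4 M) and 25(OH)D replicate 8 (1.34 M). The neuron list was high in combination replicate 1 (8.24). The liver list was high in standard cholecalciferol replicate 6 (5.29), increased cholecalciferol replicate 6 (4.55) and 25(OH)D replicate 5 (4.05). Among named genes, in log2 CPM, VDR was low in 25(OH)D replicate 1 (−0.55). CPA1 was low in standard cholecalciferol replicate 7 (−0.24) and high in increased cholecalciferol replicate 8 (3.57) and combination replicate 3 (7.18). YPEL2 was low in 25(OH)D replicate 3 (3.90), VGF was high in standard cholecalciferol replicate 6 (8.38), and TMEM255A was high in combination replicate 3 (5.17).

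Transcripts of neurons and glia exceeded muscle transcripts in libraries labelled muscle, and the muscle list was below the neuron, oligodendrocyte and astrocyte lists in 34 of 34 libraries, which is the pattern itself. In a test chosen after that count, the summed CPM of the muscle list and both fibre lists was 0.137 to 0.578 of the sum of the 3 lists (median 0.238), below the bound of 1 set for muscle as the main source. The test is void, since 36 of the 52 muscle genes have an identifier in the name table, without the myosins MYH7 and MYH4, against 43 of 50 genes of the other lists, which lowers the ratio. Against single lists, the muscle sum was below that of neurons in 30 of 34 libraries, of oligodendrocytes in 18 and of astrocytes in 16. The list means in log2 CPM are taken over measured genes, 21 of 28 for the muscle list. That list reached at most 6.98, below the lowest value of the neuron list (7.34) and of the astrocyte list (7.98). For the genes measured, this argues against muscle as the main source with some RNA of another tissue mixed in. The share of RNA from each tissue was not estimated, since the missing genes were not weighed and no reference library of muscle or brain was used here. Nerve inside the muscle is not weighed here, and no biological explanation was tested, since the design names none.

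Cerebellar and forebrain transcripts stood at opposite levels between libraries. The main axis of variation between libraries (first principal component of log2 CPM) held 21.5% of the variance. Its absolute correlation was 0.985 with the regional difference and 0.264 with the muscle list. Diet as the main cause would keep the libraries of a diet together, but the SD inside a diet was 1.75 to 2.62, against 2.04 over all libraries. The smallest range inside a diet was 5.06, against 1.10 for the largest difference of diet means. A range over 8 to 10 libraries exceeds a difference of means unless the diets hardly overlap. A smaller effect of diet is therefore not excluded. Depth would narrow the range in file numbers 1 to 24, which was 6.30, the same as over all libraries. Of check genes not used to find the pattern, 88.2% (30 of 34) followed it in the stated direction, 17 of 17 for cerebellum and 13 of 17 for forebrain, so that RNA of different parts of the brain, as the main source or mixed in, may be present.

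Genes that were lower in females were counted in females too, at a higher level in file numbers 30 to 34. Exchanged sex labels would place castrated males at female levels, and 0 of the 16 lay at or below the highest female outside that run. This speaks only to an exchange with those females, and the genes were chosen by the labelled sexes. An exchange inside the run cannot be judged, since its castrated male (151 CPM) lay within the range of its females (89.3 to 177 CPM). Reads shared with a second gene copy would give a like level in all females, but the ratio of the 4 females of that run to the other 14 was 3.34, which argues against it for the difference between runs and not for the level in the other 14. The females of the run lay above the others (exact permutation p = 0.000327, two-sided), which is the pattern itself. Reads carried over between libraries and other differences of that run cannot be told apart, since the run holds 1 castrated male. The 5 libraries of the run were also alike in regional difference (SD 0.687, against 2.13 in file numbers 1 to 24 and 2.41 in 25 to 29). By the chi-square value of counts, the closest pair of all libraries, from different diets, lay in the run as well. That value falls with lower depth, and this run was the shallowest, so that it cannot show shared RNA or reads. By correlation of log2 CPM the closest pair was standard cholecalciferol replicate 7 and combination replicate 4, both of file numbers 25 to 29. Whether these libraries share RNA or reads was not tested. If so, the spread inside the combination, with 4 of its 8 libraries there, would be understated in its p-values.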

How the results depend on the processing

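The settings that add a regional or muscle covariate, or that leave out libraries by detected genes, by regional difference or by replicate, and those for the muscle list, were chosen after the data were seen. Of 108 alternative counts of genes, 104 stayed within 1.5 times the main count, and the diet counts were 0 in all but 3. The term for file-number runs gave 1 gene for the combination against increased cholecalciferol and 18 genes for sex (3 higher, 15 lower), and file numbers 1 to 24 gave 2 genes for the combination against increased cholecalciferol and 8 for 25(OH)D against the combination. Of 90 counts of lists, 57 stayed within 1.5 times. An estimated correlation and fry each gave 0 for the 5 comparisons with a call. For the combination against standard cholecalciferol the count of lists went from 4 to 2 with limma-voom, with only the 2 groups, with file numbers 1 to 24, with both covariates and without libraries of few genes, and to 1 with the run term, without combination replicate 3 and at a regional difference of 1 or less. For the combination against increased cholecalciferol it went from 0 to 2 with limma-voom, with the run term and without combination replicate 3, and to 1 with file numbers 1 to 24, with both covariates and at a regional difference of 1 or less. For 25(OH)D against standard cholecalciferol it went from 1 to 3 with only the 2 groups, with the run term and without libraries of few genes, to 2 with file numbers 1 to 24 and to 0 at a regional difference of 1 or less. For increased against standard cholecalciferol it went from 2 to 1 with only the 2 groups and with both covariates, and for 25(OH)D against the combination from 2 to 1 with only the 2 groups and without libraries of few genes. The cause was not tested, except that fewer libraries enter some fits. At a regional difference of 1 or less, 2 combination libraries remain, and within file numbers 1 to 24, 3 remain.

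Of 689 alternative values of named genes, 653 kept direction and side of the threshold and 31 changed sign, all of them in VDR, CYP2R1 or FBXO32 and none past the threshold. With limma-voom the log2 fold changes were −0.049 (FBXO32, increased against standard), −0.060 (CYP2R1, combination against standard), 0.074 (VDR, combination against standard), 0.0056 (FBXO32) and 0.33 (VDR) for the combination against increased. Without the sex term they were −0.029 (FBXO32, increased against standard) and −0.00068 (CYP2R1, combination against standard). With the run term they were −0.11 (FBXO32, increased against standard), −0.20 (CYP2R1, combination against standard), −0.13 (FBXO32, 25(OH)D against standard) and −0.021 (FBXO32, 25(OH)D against increased). In file numbers 1 to 24 they were −0.10 (FBXO32) and 0.054 (VDR) for increased against standard, −0.18 (CYP2R1, combination against standard), −0.10 (FBXO32, 25(OH)D against standard) and −0.0017 (FBXO32, 25(OH)D against increased). With the regional covariate FBXO32 was at 0.087 (combination against standard), 0.060 (combination against increased) and −0.045 (25(OH)D against combination). With both covariates FBXO32 was at −0.11 (increased against standard), −0.056 (25(OH)D against standard) and 0.027 (combination against increased), and the fast-twitch list had a mean of −0.039 for increased against standard, where genes of the list that also enter the muscle covariate pull the mean toward 0 by construction. Without libraries of few genes CYP2R1 was at −0.13 (combination against standard) and VDR at 0.075 (combination against increased). Without combination replicate 3 VDR was at 0.060 (combination against increased). At a regional difference of 1 or less the values were −0.27 (FBXO32) and 0.18 (VDR) for increased against standard, −0.019 (CYP2R1) and 0.75 (VDR) for the combination against standard, −0.054 (FBXO32, 25(OH)D against standard) and 0.57 (VDR, combination against increased). That fit keeps 2 combination libraries, against 5 of the control and 7 of increased cholecalciferol, and VDR averaged at most 3.85 CPM in any diet. In file numbers 1 to 24 the difference in total counts was 0.307 M for increased against standard and 1.14 M for 25(OH)D against the combination, and the difference in detected genes for the latter was −172, all with the opposite sign. Of 165 alternative values of called lists, 113 kept direction and side of the threshold, 51 no longer passed and 1 changed sign. The proteasome list was among those lost most often, in 7 alternatives. KDM5D was no longer past the threshold in 3 fits, with adjusted p from 0.0586 to 0.119. Depth limits what can be said of CYP24A1 and CYP27B1, with 43 and 15 counts in all libraries, which did not pass the filter.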

Other observations

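Every test in this part was chosen after the results were seen. Pancreatic enzyme transcripts varied between libraries. CPA1 ran from 0.476 to 145 CPM and PNLIP from 0 to 72.0 CPM, with both highest values in combination replicate 3. Among genes known as vitamin D targets, CALB1, a calcium-binding protein gene, had a median of 47.8 CPM and reached 371 CPM, S100G had a median of 0.680 CPM and reached 50.2 CPM, and the calcium channel gene TRPV6 had 253 counts over 34 libraries. Whether these levels follow vitamin D or the regional difference between libraries was not tested.

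In each comparison, libraries were drawn again into groups of the same sizes, 30 splits in all for counts of genes and 100 for counts of lists, the real split included.

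For the 6 diet comparisons all 30 splits gave at least the real count of 0 genes, so that the counts exclude nothing. The highest count of another split was 71 for increased against standard cholecalciferol, 1801 for the combination against standard cholecalciferol, 0 for 25(OH)D against standard cholecalciferol, 1 for the combination against increased cholecalciferol, 0 for 25(OH)D against increased cholecalciferol and 2 for 25(OH)D against the combination. The split with 1801 genes separated libraries with a mean regional difference of −0.07 from libraries with 3.54. The sides, of 8 libraries each, also held 1 and 3 libraries of file numbers 30 to 34, and the muscle list averaged 5.69 and 6.06. So many calls point to a structure of the samples other than diet, and which of these differences accounts for it was not tested. For sex, 1 of 30 splits reached 11 genes, the real one, and the highest other was 0, which makes chance unlikely, though 30 splits cannot exclude it. For the interaction 30 of 30 splits reached 0 and the highest other was 0.

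Counts of called lists were common in other splits, too. As many lists as the real split were called in 72 of 100 splits for increased against standard cholecalciferol (real 2, highest other 12), in 45 for the combination against standard cholecalciferol (real 4, highest other 10), in 77 for 25(OH)D against standard cholecalciferol (real 1, highest other 8), in 100 for the combination against increased cholecalciferol (real 0, highest other 10), in 63 for 25(OH)D against increased cholecalciferol (real 2, highest other 9) and in 64 for 25(OH)D against the combination (real 2, highest other 10). Chance cannot be excluded for any of these counts.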
